A study of Brassica rapa with 6 samples.

How the data were processed

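Whole-transcriptome libraries of Chinese cabbage (Brassica rapa) were compared between leaf and petiole, the stalk and midrib part of the leaf, with 3 libraries per tissue. Per the labels' protocols, plants were grown in a greenhouse, ribosomal RNA was depleted from total RNA and strand-specific libraries were made, so RNA without a poly(A) tail, including circular RNA and plastid RNA, stays in the sample. Samples were grouped by the tissue in their titles. The labels do not say that the libraries came from separate plants. P-values of tests between libraries therefore measure only the spread between these samples, which may be technical. P-values of gene lists with a preset correlation, of pathway and family tests and of permutations over circRNAs compare genes or circRNAs with each other instead.

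The authors deposited one table of circular RNAs (circRNAs) and one of linear transcript isoforms. Per the file headers, the circRNA table gives back-spliced junction read counts per library, the position, a type (circRNA for exons, ciRNA for introns, or intergenic) and a host gene. The authors also deposited a signal scaled to library size (SRPBM), in which every value of a library is the count times 1 constant; this signal was used only in an alternative. Per the file headers, the isoform table holds estimated counts and FPKM values per transcript. The deposited estimated counts are whole numbers, so no rounding was needed, and in every library they follow FPKM times transcript length within 1% for 100% of the isoforms with at least 1000 counts. In the deposited FPKM columns, an isoform with a count of 0 holds 0.0001, which was set to 0 here. HISAT2, StringTie and TopHat are named in the submitters' processing notes without versions or roles. The circRNA caller and the genome build are not given in the sources used here, and coordinates are printed as the files give them.

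Linear totals ranged from 111518411 to 132861243 estimated counts per library, and back-spliced reads from 3216 to 4227. A count of 0 therefore allows a linear level of up to 0.0226 to 0.0269 CPM of all linear counts of a library, without TMM, and a share of up to 0.071% to 0.0933% of the back-spliced reads of a library, taking 3 counts as the floor. Intervals and floors cover counting error only. Some zeros went beyond it, as circRNA68 had 267, 0 and 298 reads in the leaf libraries, so the floors may not be upper limits.

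Gene values are sums of estimated counts over isoforms that match the annotated gene, share a junction with it or lie within it (45517 genes). This definition was chosen after the tables were seen and before any test. Gene names are the descriptions in the isoform table: 26887 genes (59.1%) have a description that names a protein. The tests had been planned on FPKM values, with edgeR to be used if the table held counts. Because it does, genes and isoforms with a mean of at least 10 counts over the 6 libraries were tested with edgeR 4.0.16 (TMM normalization, quasi-likelihood F test, petiole minus leaf, Benjamini-Hochberg adjustment, called at adjusted p below 0.05) in R 4.3.3. The same test was used for circRNAs with a read in at least 3 of the 6 libraries. Gene levels are TMM-normalized CPM of the counts in gene values, which are fewer than all linear counts. Where every library of a tissue was at 0, the fold is given as a lower bound. It is set against 3 counts over the 3 libraries of that tissue, 0.0141 CPM in leaf and 0.0102 CPM in petiole. This bound covers counting error only, and does not hold where the quantification lists a low level as 0.

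Gene lists were fixed before the data were examined, as were the tests, the alternatives not marked as added, and the rule for named genes. Of 28 lists, 26 had at least 3 tested members. They were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, repeated with an estimated correlation), adjusted over the lists. With the preset correlation, camera's p-value rests on the spread among genes. With an estimated correlation it takes only the degrees of freedom left by the 6 libraries. The rule names the 10 largest rises and 10 largest falls among called genes with a name and with no overlap between tissues, up to 2 called rises and 2 called falls from each list, and, for circRNAs, the 5 called with the largest change in each direction, filled up by the smallest unadjusted p, and the 5 most abundant. The number of circRNAs per library was compared with an exact permutation test, and circRNA changes were set against host gene changes by correlation with 100000 permutations. Shares of reads in a single library have 95% Wilson intervals. Pathway and family enrichment used Fisher's exact test in SciPy 1.17.1 (Python 3.11.15).

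The methods were tested on simulated data. In counts drawn from the real means and library sizes, with 200 of 27984 genes changed, edgeR recovered 19.4% of genes changed 1.5-fold, 50.0% of those changed 2-fold and 77.9% of those changed 4-fold, all with the right sign; 11.5% of its calls were unchanged genes. With 200 of 52982 isoforms changed, it recovered 0 of 67 isoforms changed 4-fold. With 15000 isoforms changed, it recovered 1163 of 5082 changed 4-fold, and 2.8% of its calls were unchanged isoforms. With noise taken from the observed spread between replicates instead, 23.5%, 55.0% and 73.6% of such genes were recovered, 4 of 74 isoforms changed 4-fold with 200 changed, and 2565 of 5114 with 15000 changed. That noise and the larger number of changed isoforms were added after the first simulation had recovered 0 isoforms. With that noise, counts were first thinned until both tissue means were equal, which removed random differences between the means. Of its unchanged genes and isoforms 0% had an unadjusted p below 0.05. Its shares therefore do not show how many would be recovered with such random differences present. For 57 circRNAs, 0 of 8 changed 16-fold were recovered. A list of 30 genes raised 1.5-fold was called by camera, and 0 of 20 lists of unchanged genes were. The unchanged lists were random genes, without the correlation that members of a real list can share. They could therefore not show false calls that such correlation causes.

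Alternatives were no filter on low counts, a mean of at least 2 FPKM, DESeq2 size factors, DESeq2 1.42.0, a fold of at least 2, the replicate number as a block, leaving out each library in turn, other filters for circRNAs and linear library sizes for circRNAs. Added after seeing the data were limma on log2(FPKM + 1) and log2(FPKM + 0.1), all assembled isoforms under a gene's name, the denominators behind SRPBM, circRNA totals without TMM, DESeq2 with linear library sizes, circRNAs of any library, circRNAs outside a block of chromosome A06, and libraries thinned to equal reads, over all circRNAs and outside that block.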

Results

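Leaf and petiole of Chinese cabbage are parts of the same organ: the green blade carries out photosynthesis, and the pale, thick petiole supports and supplies it. Linear transcripts and circRNAs of 3 leaf and 3 petiole libraries were compared to ask how the transcriptomes of the tissues differ, as the series' design states. Circular RNAs are closed molecules made when the end of an exon or intron is joined back to an upstream start, and are counted by reads across that back-spliced junction. The leaf libraries held 114915496, 121161682 and 111518411 estimated linear counts and 3739, 3216 and 4227 back-spliced reads. The petiole libraries held 132861243, 129793260 and 120805715 linear counts and 3618, 3493 and 3396 back-spliced reads. Log2 gene levels correlated across genes at 0.953 to 0.958 between libraries of one tissue and at 0.773 to 0.779 between tissues.

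The first comparison asked which genes differ between petiole and leaf. Among the fixed gene lists, those of photosynthesis were lower in petiole, and those of jasmonate signalling, glucosinolate synthesis, cell wall remodelling, lignin synthesis and water transport were higher. Of 71 tested light harvesting and photosystem genes, 67 fell, with a median log2 fold change of -3.24, and 0 rose. A pectinesterase 47 gene (BraA10g031400.3C), of a family that modifies pectin in the cell wall, stood at 90.3 ± 2.77 CPM (SD, n = 3) in petiole and at 0 in every leaf library, at least 6410-fold higher in petiole. Across 27984 tested genes, 8787 were higher and 8683 lower in petiole by edgeR at adjusted p below 0.05, 62.4% of the genes tested. On the FPKM scale, where the median gene was 0.48 higher in petiole on the log2(FPKM + 1) scale, limma called 16497 genes higher and 4257 lower, so that 79.5% of calls were rises against 50.3% with edgeR. Directions given here are relative to the bulk of the genes, and the 14 gene lists called below kept theirs on the FPKM scale relative to its median. List medians were the same with genes at 0 in 1 tissue set to their lower bounds. These bounds, printed as at least a fold, take each 0 as a counted value. A minimum below which the quantification lists 0 could not be told apart from true absence, so the true folds may be smaller.

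Among the largest rises in petiole by the fixed rule were ethylene-responsive transcription factor 13-like (BraA09g000880.3C, A09 513242 to 515036; at least 1960-fold), expansin-A5, a wall-loosening protein (BraA06g036610.3C, A06 24549355 to 24551449; at least 1090-fold), calcium-binding protein CML39 (BraA07g040250.3C; at least 937-fold) and the anion channel SLAH2 (BraA08g019220.3C; at least 713-fold). Their petiole levels were 27.7 ± 5.61, 15.3 ± 1.62, 13.2 ± 0.492 and 10.1 ± 1.49 CPM (SD, n = 3), and each was at 0 in all leaf libraries. At the places of the ERF13-like and CML39 genes, however, other assembled transcripts held 12.8% and 22.3% of the petiole level in leaf. The largest falls included CONSTANS-LIKE 6-like (BraA07g030750.3C, A07 22465123 to 22468033), at 24.5 ± 9.06 CPM in leaf, TIC 32, a component of the chloroplast import machinery (BraA10g033110.3C, A10 20416438 to 20418915), at 22.6 ± 0.696 CPM, a chlorophyll a-b binding protein (BraA08g028350.3C) at 22.5 ± 2.19 CPM and cellulose synthase-like protein G2 (BraA01g014690.3C) at 22.5 ± 1.22 CPM (SD, n = 3). All of these were at 0 in every petiole library, at least 2400-fold, 2220-fold, 2210-fold and 2200-fold lower. The transcription factor bHLH57 (BraA09g001050.3C; at least 1920-fold) and NGA1-like (BraA04g032340.3C; at least 1240-fold), from a family of leaf margin regulators, were also at 0 in petiole. The adjusted p of edgeR for these genes lay between 2.04e-07 and 1.53e-05.

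The lists of Calvin cycle, chlorophyll synthesis and photorespiration genes were also shifted downward. Of 27 Calvin cycle genes 23 fell (24 adjusted over the list alone), with a median log2 fold change of -3.28, and 1 rose. A Rubisco small chain F1 gene (BraA07g019510.3C) went from 318 ± 22.9 CPM in leaf to 0.204 ± 0.028 CPM in petiole (SD, n = 3), a log2 fold change of -10.59 (SE 0.107). The 1 rise was a partial copy of the plastid Rubisco large subunit gene (BraA01g028300.3C), with 1 count in each leaf library and 6559, 7323 and 1 counts in the petiole libraries. It is uncertain because reads of the plastid gene can be shared with it, and its log2 change was -2.50 when all transcripts under its name were summed. Of 27 chlorophyll synthesis genes 24 fell and 1 rose (24 and 2 adjusted over the list alone, median -1.99). The falls included protochlorophyllide reductase C (BraA08g035300.3C, -3.84, SE 0.107). Of 36 photorespiration genes 21 fell and 9 rose (21 and 9 adjusted over the list alone, median -1.75), with a serine-glyoxylate aminotransferase-like gene (BraA03g042340.3C) at -7.87 (SE 0.191). The camera test placed all of these lists below the other genes, with adjusted p of 1.31e-86 for light harvesting (67 adjusted over the list alone), 3.39e-53 for the Calvin cycle, 9.05e-14 for chlorophyll synthesis and 4.89e-14 for photorespiration. With an estimated correlation, which takes only the degrees of freedom of the 6 libraries, the adjusted p were 0.00552, 0.00335, 0.0117 and 0.014.

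Genes of jasmonate, a hormone of defence and wounding, rose: 39 of 48 tested members were higher and 2 lower in petiole (39 and 3 adjusted over the list alone, median log2 fold change 2.86; camera adjusted p = 2.22e-25, and adjusted p = 0.00552 with an estimated correlation). A TIFY 5B-like gene (BraA04g024740.3C), from the family of jasmonate repressors, was at 2.80 ± 0.525 CPM in petiole (SD, n = 3) and at 0 in leaf, at least 199-fold higher. A JAR1-like jasmonate conjugating gene (BraA04g032040.3C) fell by 3.77 on the log2 scale (SE 0.221). Heat shock and handling stress genes were not shifted as a list (19 of 45 higher, 11 lower; 21 and 11 adjusted over the list alone, camera adjusted p = 0.434). Glucosinolates are the sulfur-containing defence compounds of cabbages. Of 9 aliphatic glucosinolate genes 8 rose (8 adjusted over the list alone, median 3.13; camera adjusted p = 0.000106), including sulfotransferase 17 (BraA06g014220.3C), from 2.01 ± 0.404 to 61.1 ± 0.392 CPM (SD, n = 3), and the methionine aminotransferase BCAT4 (BraA03g039020.3C, 4.76, SE 0.859). Of 19 indolic glucosinolate genes 12 rose and 3 fell (13 and 3 adjusted over the list alone, median 1.34; camera adjusted p = 1.58e-05), with a cytochrome P450 81F1-like gene (BraA01g001490.3C) going from 0.390 ± 0.168 to 149 ± 6.47 CPM (SD, n = 3). With an estimated correlation the adjusted p of these lists were 0.0318 and 0.0254. The estimated correlations were -0.099 and -0.033, below the preset 0.01, so correlation within these lists did not raise the p-values.

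Wall and water transport genes were mixed in direction but shifted upward. Expansins and xyloglucan endotransglucosylases, which loosen walls during growth, had 41 of 67 members higher and 14 lower (42 and 15 adjusted over the list alone, median 1.33), and 2 expansin-A16 genes were among the falls. One of them, BraA04g004550.3C, was at 0.99 when all transcripts under its name were summed. Pectin-modifying genes had 57 of 111 higher and 21 lower (58 and 21 adjusted over the list alone, median 0.79). Lignin synthesis genes had 39 of 61 higher and 8 lower (39 and 9 adjusted over the list alone, median 1.29): cinnamoyl-CoA reductase 2 (BraA07g042720.3C) and a cinnamoyl-CoA reductase-like gene (BraA02g005610.3C) rose by log2 8.01 and 6.13, while cinnamoyl-CoA reductase 1 (BraA09g062380.3C) was at -3.48. Aquaporins, the water channels of membranes, had 25 of 38 higher and 7 lower (25 and 7 adjusted over the list alone, median 0.77), with PIP2-2-like (BraA03g019370.3C) rising by 4.11 on the log2 scale (SE 0.085). Auxin response genes had 71 of 147 higher and 31 lower (71 and 31 adjusted over the list alone, median 1.24). The camera adjusted p were 5.44e-06, 3.16e-05, 2.11e-05, 1.14e-06 and 0.0215 in this order, and 0.0258, 0.014, 0.0247, 0.0316 and 0.0363 with an estimated correlation.

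Dividing cell genes (26 of 33 higher, 1 lower; 27 and 1 adjusted over the list alone, median 1.80; camera adjusted p = 0.000304) and cytosolic ribosomal protein genes (205 of 266 higher, 5 lower; 208 and 5 adjusted over the list alone, median 0.56; camera adjusted p = 3.73e-06) also stood above the other genes. With an estimated correlation these calls were lost (adjusted p = 0.204 and adjusted p = 0.235). An Aurora-3 kinase gene (BraA05g005240.3C), which acts in mitosis, rose from 0.126 ± 0.116 to 3.71 ± 0.578 CPM (SD, n = 3). The other 12 lists were not shifted by camera, which asks whether a list moved more than the other genes. Their members can still differ between the tissues. Markers of guard cells, epidermis and phloem gave no list shift: for guard cells 12 of 26 genes were higher and 6 lower (12 and 6 adjusted over the list alone, median 0.57, mean -0.25; adjusted p = 0.563), for epidermis, wax and trichomes 34 of 74 and 20 (35 and 20 adjusted over the list alone, adjusted p = 0.396), and for phloem 5 of 18 and 8 (5 and 8 adjusted over the list alone, adjusted p = 0.226). Within them, the guard cell anion channel SLAC1 (BraA06g009180.3C) was at least 627-fold lower in petiole, an ECERIFERUM 3-like wax gene (BraA03g012220.3C) was at -9.81 (SE 0.687), and the phloem sucrose transporter SUC2 (BraA07g014520.3C) went from 136 ± 4.96 to 29.8 ± 1.56 CPM (SD, n = 3). Rises in these lists included EPIDERMAL PATTERNING FACTOR-like 6 (BraA04g021610.3C, 2.42, SE 0.441), PHLOEM PROTEIN 2-LIKE A8 (BraA09g020890.3C, 3.62, SE 1.12) and trichome birefringence-like 39 (BraA04g029940.3C, at least 130-fold higher in petiole), of a family known for acetylating wall polymers. The call of PHLOEM PROTEIN 2-LIKE A8 was lost without leaf replicate 1 (3.35, edgeR adjusted p = 0.0636) and without petiole replicate 3 (3.46, edgeR adjusted p = 0.0629). The 1 tested xylem marker, a xylem cysteine proteinase 2-like gene (BraA07g015520.3C), was at 0.63 (SE 0.149).

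Secondary wall cellulose and xylan genes had 12 of 20 higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.133), histones 18 of 42 and 10 (18 and 10 adjusted over the list alone, adjusted p = 0.423), and myrosinases and specifier proteins 6 of 10 and 2 (6 and 3 adjusted over the list alone, adjusted p = 0.278). Leaf polarity and boundary regulators had 6 of 19 higher and 6 lower (6 and 6 adjusted over the list alone, adjusted p = 0.967), with a knotted-1-like 6 homeobox gene (BraA09g039740.3C) at 5.31 (SE 0.877) and knotted-1-like 3 (BraA02g041780.3C) at -2.19 (SE 0.081). Starch genes had 16 of 37 higher and 18 lower (16 and 19 adjusted over the list alone, adjusted p = 0.712), flavonoid and anthocyanin genes 6 of 17 and 7 (7 and 7 adjusted over the list alone, adjusted p = 0.966), sulfate and nitrate genes 13 of 36 and 15 (13 and 16 adjusted over the list alone, adjusted p = 0.966) and splicing genes 9 of 74 and 29 (9 and 27 adjusted over the list alone, adjusted p = 0.243). The medians of these last 4 lists and of the phloem list were below 0 with edgeR and above 0 on the FPKM scale. Relative to the median of all genes on that scale, the flavonoid, sulfate and phloem medians stayed below 0 (-0.43, -0.17 and -0.31), and the starch and splicing medians were at 0.01 and 0. The flavonoid and sulfate lists had medians below 0 beside an upward camera statistic. Xylem markers as a list and genes encoded in the plastid or mitochondrion (0 genes matched) were not tested.

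**Figure D1:**
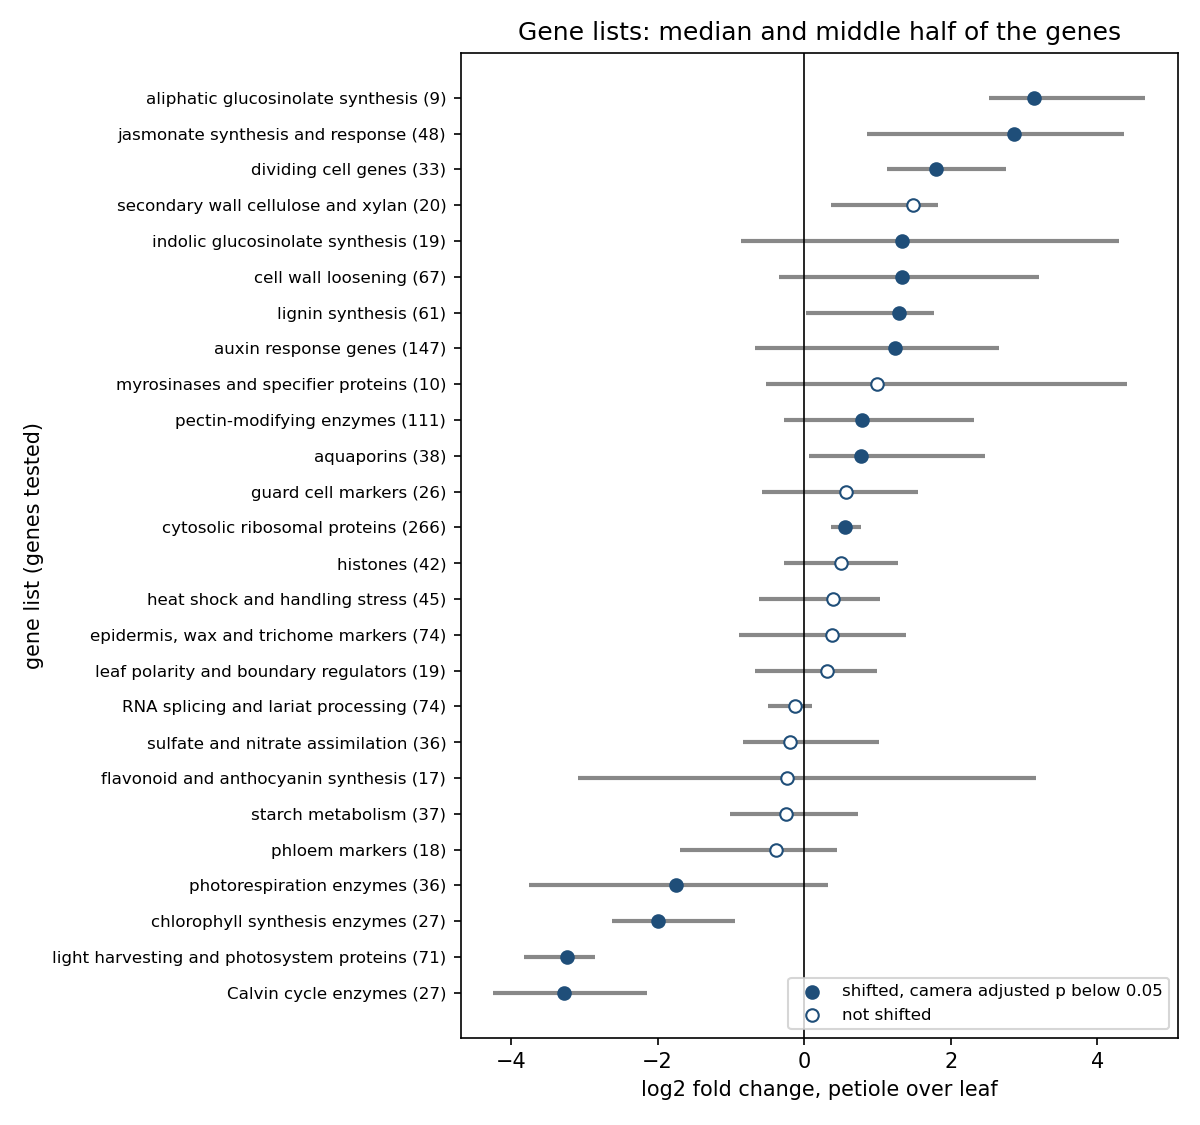
Median log2 fold change, petiole over leaf, of the tested genes of 26 gene lists (points; filled where camera's adjusted p was below 0.05), with bars from the lower to the upper quartile of the genes and the number of tested genes in brackets. Light harvesting and Calvin cycle genes lie at medians of -3.24 and -3.28, jasmonate and aliphatic glucosinolate genes at 2.86 and 3.13.

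Single isoforms were also called in both directions. Of 52982 tested isoforms, 8181 were higher and 7468 lower in petiole by edgeR (29.5%). Counting all assembled transcripts under a gene's name, also those left out of gene values, 13317 genes had at least 2 tested. Of these, 242 (1.8%) had one called higher and another called lower, or 14.7% of the 1641 genes with at least 2 called. Isoforms in places with no annotated gene were called in both directions, 428 higher and 509 lower of 3549 tested. DESeq2 called 12529 isoforms higher and 11585 lower. On the log2(FPKM + 1) scale limma called 17893 higher and 4934 lower, so that 78.4% of calls were rises against 52.3% with edgeR.

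The next comparison asked how many circRNAs each tissue shows. Leaf libraries detected 231, 261 and 244 circRNAs and petiole libraries 122, 134 and 129, a mean of 245 ± 15.0 against 128 ± 6.03 (SD, n = 3 per tissue; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Over circRNAs found in at least 2 libraries the means were 70 ± 4.58 and 54.7 ± 1.53 (SD, n = 3). The excess in leaf lay in 1 block of chromosome A06 (15079018 to 15619492), where the descriptions of 4 annotated genes in a row name proteins that plastids encode: CP43 of photosystem II, an RNA polymerase beta subunit, ATP synthase CF0 subunit C and atpA. This block held 395 of the 886 circRNAs (44.6%), 383 of them called intergenic. Leaf libraries detected 139, 151 and 137 circRNAs there and petiole libraries 3, 5 and 5. Outside the block the direction turned, with 92, 110 and 107 in leaf and 119, 129 and 124 in petiole, a mean of 103 ± 9.64 against 124 ± 5 (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible). Leaf libraries held fewer reads outside the block (1785, 1951 and 1914) than petiole libraries (3593, 3446 and 3327), and thinned to equal reads there the means were 102 ± 9.03 and 112 ± 3.93 (SD, n = 3). The block was singled out after its values were seen.

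**Figure D2:**
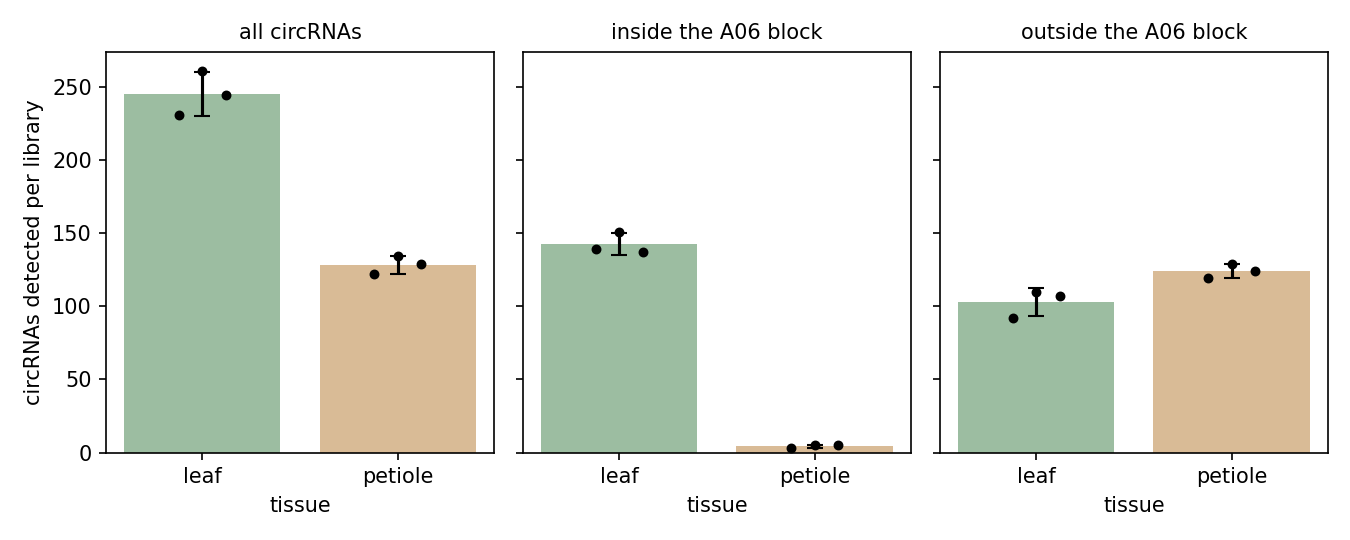
Number of circRNAs detected per library in leaf and petiole (points, single libraries; bars, mean; error bars, SD, n = 3) for all circRNAs, those inside the A06 block and those outside it. Leaf exceeds petiole overall and inside the block (mean 142 against 4.33), while outside it petiole (mean 124) exceeds leaf (mean 103).

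The share of reads from the block differed as well. The block held 52.3% (Wilson 95% interval 50.7 to 53.9), 39.3% (37.7 to 41.0) and 54.7% (53.2 to 56.2) of the back-spliced reads of the leaf libraries, but 0.691% (0.468 to 1.02), 1.35% (1.01 to 1.78) and 2.03% (1.61 to 2.56) of those of the petiole libraries. Linear transcripts of the block took 22.1% ± 3.88 of all linear counts in leaf and 3.96% ± 0.0665 in petiole (SD, n = 3). By type, 563 of the 886 circRNAs were called intergenic, 211 came from exons and 112 from introns. Exon circRNAs outside the block were detected 29, 38 and 30 times in leaf and 38, 45 and 51 times in petiole. Intron circRNAs were detected 19, 25 and 28 times in leaf and 22, 22 and 21 times in petiole. Most circRNAs were seen in a single library: 747 (84.3%) had reads in 1 library only, 57 in at least 3 libraries and 5 in all 6.

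**Figure D3:**
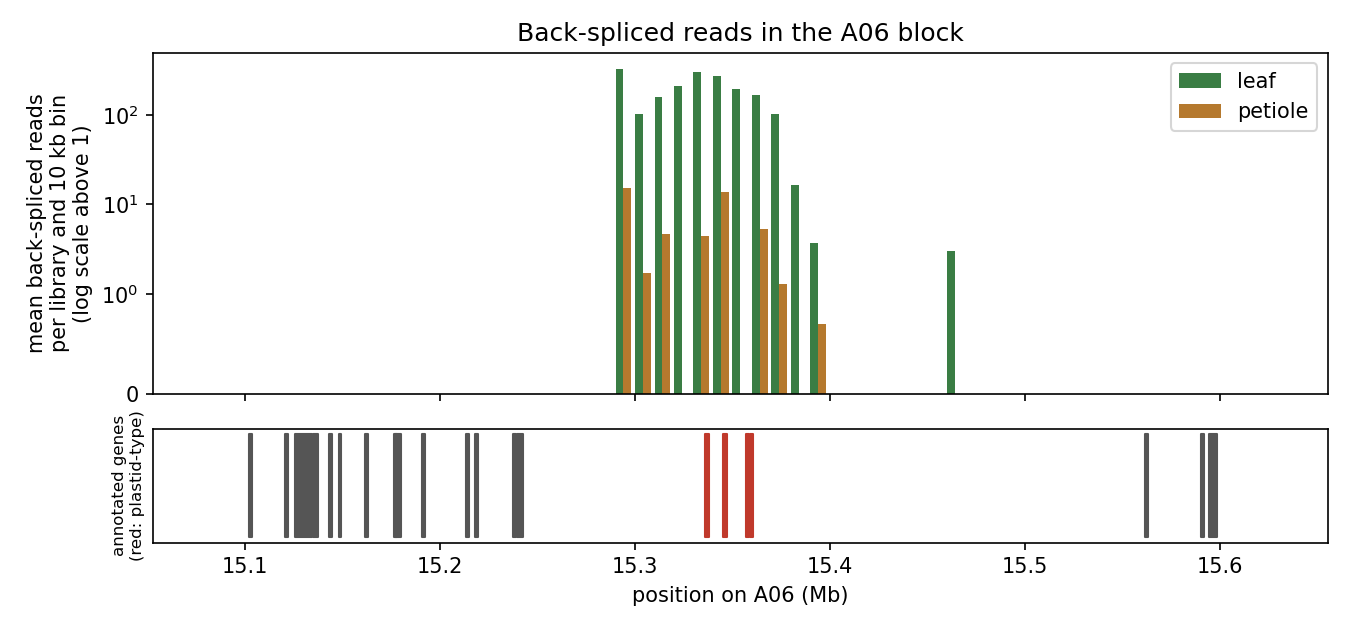
Back-spliced reads along the A06 block, as the mean per library and 10 kb bin in leaf and petiole (log scale above 1 read), above the annotated genes; genes whose descriptions name plastid-encoded proteins are in red. Leaf bars exceed petiole bars in every bin with reads, and the circRNAs lie between positions 15287149 and 15557078, around the plastid-type genes.

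Of single circRNAs, 1 intron circle rose in petiole. ciRNA14 (A06 1394381 to 1395427, inside the uncharacterized gene BraA06g002280.3C) had 407, 401 and 425 reads in leaf and 1462, 1528 and 1409 in petiole, a log2 fold change of 1.33 (SE 0.10; edgeR adjusted p = 0.000129). Its host gene rose alongside, from 429 ± 48.1 to 981 ± 52.2 CPM (SD, n = 3; log2 fold change 1.19, SE 0.081). ciRNA14 made up 10.1% to 12.5% of the back-spliced reads in leaf libraries and 40.4% to 43.7% in petiole libraries. Of the reads outside the block, it made up 20.6% to 22.8% in leaf and 40.7% to 44.3% in petiole. The other abundant intron circle, ciRNA16 (A04 20895497 to 20898866, inside BraA04g030560.3C), had 484, 564 and 462 reads in leaf and 728, 753 and 606 in petiole. Its log2 change was -0.03 (SE 0.13) with TMM but 0.32 per linear library size and 1.14 with the denominators behind the deposited SRPBM values, so no direction was settled. The change of ciRNA14 was 1.69 and 2.51 on those scales. ciRNA16 was called higher in petiole with the SRPBM denominators and by DESeq2 with linear library sizes (DESeq2 adjusted p = 0.023), and in no other setting. The SRPBM denominators were lower in petiole (0.623 times leaf), whereas linear totals were higher, and what the denominators count is not given in the sources used here.

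**Figure D4:**
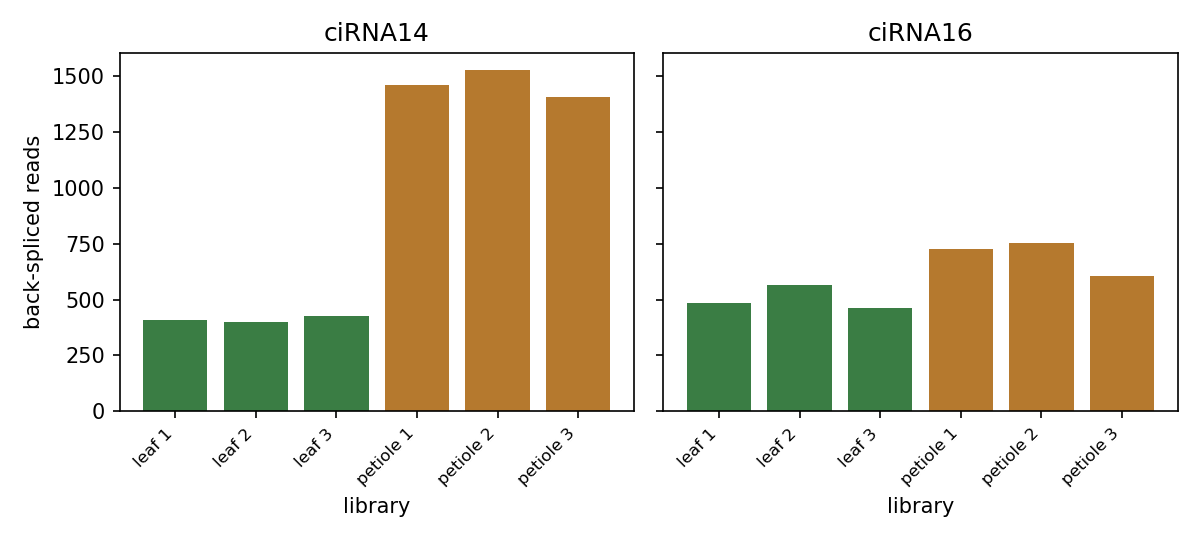
Back-spliced reads of ciRNA14 and ciRNA16 in each of the 6 libraries (bars, 1 library each, not normalized). ciRNA14 lies between 401 and 425 reads in leaf and between 1409 and 1528 in petiole, and ciRNA16 between 462 and 564 in leaf and 606 and 753 in petiole.

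Among 57 tested circRNAs edgeR thus called 1 higher and 0 lower, with 4 higher and 3 lower at an unadjusted p below 0.05, and DESeq2 called 2 higher and 3 lower. Among these, circRNAs called intergenic had reads in every petiole library and in no leaf library: circRNA601 (A01 9905390 to 9909948; 22, 15 and 29 reads), circRNA612 (A05 5873725 to 5883711; 15, 4 and 14) and circRNA634 (A09 10513996 to 10522503; 6, 10 and 5), with edgeR adjusted p of 0.121, 0.121 and 0.154. The reverse held for circRNA45 (A06 3646065 to 3651342; 18, 13 and 7 reads in leaf) and, inside the plastid-type block, circRNA58 (32, 24 and 33) and circRNA136 (11, 16 and 35), each at an edgeR adjusted p of 0.121. Though called intergenic, circRNA45 overlaps a cinnamoyl-CoA reductase 1-like gene (BraA06g006390.3C, A06 3650219 to 3652314) that was itself lower in petiole (log2 change -4.41, SE 0.19). Other abundant circRNAs were uneven between libraries of one tissue: circRNA68, in the block, had 267, 0 and 298 reads in leaf, and circRNA249 (A05 4897871 to 4903189) had 0, 226 and 127 in leaf and 0, 256 and 214 in petiole. Without petiole replicate 1, ciRNA14 was at 1.61 with an edgeR adjusted p of 0.112, and 0 circRNAs were called higher; over the other alternatives its adjusted p ranged from 6.74e-198 to 0.0326.

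The last comparison asked whether circRNAs change with their host genes. ciRNA14 and its host both rose, and circRNA201 and its host, a phosphate transporter PHO1-like gene (BraA08g025870.3C), had log2 changes of -0.99 and -0.98, whereas 4 circRNAs of the extensin-2-like gene BraA04g030500.3C, a wall protein gene at -0.92 (edgeR adjusted p = 0.0747), had changes between -1.50 and 0.98. These host genes were picked out after their values were seen. Over 13 tested circRNAs in 8 host genes, Pearson's r was 0.512 (permutation p = 0.0725) and Spearman's rho 0.531 (permutation p = 0.0651), with the same sign in 9 of 13. This is a correlation across circRNAs, which are not independent replicates, and it did not pass 0.05. With the most abundant isoform of each host r was 0.524 (permutation p = 0.0494), and over 322 circRNAs of any library, an alternative added after the data were seen, it was 0.42 (permutation p = 1e-05, the smallest the permutations can give). With 1 circRNA per host gene r was 0.594 over 8 circRNAs (permutation p = 0.121), and without petiole replicate 3 it was 0.158 over 10 circRNAs (permutation p = 0.64).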

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

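The FPKM tests, the sums over all transcripts under a gene's name, the SRPBM denominators, circRNA totals without TMM, DESeq2 with linear library sizes, circRNAs of any library, thinning and the analyses without the A06 block were chosen after the data were seen. Beside the counts of called items, 1898 values of named genes, lists and circRNAs under an alternative kept their side of the threshold with no counted change of direction, 37 lost the call, 11 gained it and 25 changed direction. A list called neither in the main fit nor in the alternative stayed among the 1898 even if its direction changed.

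Gene counts without each library in turn were 8027 to 8453 higher and 8047 to 8253 lower. With a fold of at least 2 they were 4747 and 4734, which follows from the added condition. With limma on log2(FPKM + 1) they were 16497 and 4257, and on log2(FPKM + 0.1) 16560 and 4269, where the median of all genes is 0.48 and 0.72. On these scales NACK1 (BraA09g055620.3C) changed direction to 0.06 and 0.07, TIFY 3B-like (BraA10g019770.3C) to 0.24 and 0.25 and an epithiospecifier-like gene (BraA06g043050.3C) to 0.29 and 0.30, all below the median of all genes there. With all assembled transcripts under a gene's name, the Rubisco large subunit copy (BraA01g028300.3C) was at -2.50, expansin-A16-like (BraA04g004550.3C) at 0.99 and sulfate transporter 1.2 (BraA07g041120.3C) at -2.06, and the cause was not tested.

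Isoform counts without each library were 6213 to 7251 higher and 5668 to 6564 lower. They were 12529 and 11585 with DESeq2, 17893 and 4934 with limma on log2(FPKM + 1), and 17988 and 4936 on log2(FPKM + 0.1). With the replicate number as a factor (replicate block) they were 4678 and 4367. The numbers did not pair the samples: deviations of a leaf and a petiole library correlated at -0.002 to 0.006 for equal numbers and at -0.014 to 0.015 for different ones. Of the lists, 14 were shifted without each library and 15 with the block, which added secondary wall genes (camera adjusted p = 0.0219).

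The circRNAs called higher were 2 with DESeq2, 2 with the SRPBM denominators, 4 with DESeq2 and linear library sizes, and 0 to 1 without each library. Those called lower were 3 with DESeq2, 3 with DESeq2 and linear library sizes, and 1 with the block. ciRNA16 changed direction to 0.01 with no filter, 0.32 with linear library sizes in edgeR and in DESeq2, 1.14 with SRPBM denominators, 0.52 with circRNA totals, 0.19 without petiole replicate 1 and 0.12 without petiole replicate 2, with a range of -0.08 to 0.19 without each library. circRNA249, at 0 in 2 libraries, changed direction to 0.02, 0.32, 0.32, 1.27 and 0.44 under the first of these settings, 0.01 with the block, 0.77 and 0.13 without leaf replicates 2 and 3, and 0.89 without petiole replicate 1, with a range of -0.61 to 0.89 without each library. The cause was not tested.

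The difference in detected circRNAs, petiole minus leaf, was -15.3 for circRNAs found in at least 2 libraries, 21 outside the A06 block, 9.6 outside it at equal reads, and -124.2 to -109.2 without each library. The correlation of circRNA and host gene changes was 0.524 with the most abundant isoform (permutation p = 0.0494), 0.42 over 322 circRNAs of any library (permutation p = 1e-05, the smallest the permutations can give), and 0.158 to 0.707 without each library. With 1 circRNA per host gene it was 0.594 (permutation p = 0.121), and with the replicate block 0.373 (permutation p = 0.209). It had no value for circRNAs found in at least 5 libraries, where too few were left. Other pseudocounts were not run. The log2 changes of edgeR stay finite where a tissue is at 0 in every library, so they include a small added count. Its effect on the circRNA changes was not examined. By counting error alone, a 0 at these depths allows up to 0.071% to 0.0933% of a library's back-spliced reads. Some zeros went beyond this, as circRNA68 had 267, 0 and 298 reads in the leaf libraries. The share may therefore not be an upper limit.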

Other observations

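The pathway and family tests, the tests of thinned reads, of the A06 block and of circRNA lengths, and the comparison with other splits of the libraries were chosen only after the results were seen. Among KEGG pathways, those of respiration and of the ribosome had more genes higher in petiole. Of 254 Fisher tests over 127 KEGG pathways with a background of 14030 genes, 31 passed an adjusted p of 0.05. Oxidative phosphorylation had 185 of 356 genes higher (52.0% against 35.3% of the background, adjusted p = 2.95e-09), the citrate cycle 55 of 108 (adjusted p = 0.00828), the phagosome pathway 122 of 206 (adjusted p = 1.47e-10), endocytosis 313 of 735 (adjusted p = 0.000405) and steroid biosynthesis 48 of 87 (adjusted p = 0.00247). The ribosome had 362 of 679 (adjusted p = 9.51e-21), while the fixed list of cytosolic ribosomal proteins was not called by camera with an estimated correlation (adjusted p = 0.235). The proteasome had 73 of 156 (adjusted p = 0.0202), but ubiquitin mediated proteolysis 104 of 358, fewer than the background share. These tests treat genes as independent, which they are not.

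Besides photosynthesis (84 of 101 genes lower, adjusted p = 1.44e-25), the peroxisome (97 of 210, adjusted p = 3.14e-05), the circadian rhythm (100 of 220, adjusted p = 4.80e-05), carotenoid synthesis (37 of 74, adjusted p = 0.00625) and anthocyanin synthesis (15 of 23, adjusted p = 0.00828) had more lower genes than the 30.5% of the background. The fixed list of flavonoid and anthocyanin genes was not shifted (camera adjusted p = 0.966), and KEGG flavonoid biosynthesis had 40 of 108 genes higher and 34 lower, with neither direction called. Beside the shifted Calvin cycle and glucosinolate lists, the broader KEGG carbon fixation pathway had 77 of 187 genes higher and 75 lower (median log2 change 0.14, adjusted p = 0.0298 for lower), and KEGG glucosinolate biosynthesis had 20 of 40 higher and 11 lower and was not called (adjusted p = 0.187 for higher). Of 20 tests over 10 gene families, 2 passed. Components of the TIC and TOC complexes, which import proteins into plastids, had 27 of 40 genes lower (67.5% against 31.0%, adjusted p = 4.49e-05). ERF transcription factors, which act in ethylene and stress responses, had 63 of 150 genes higher (42.0% against 31.4%, adjusted p = 0.0385). On the FPKM scale relative to the median of all genes, the medians of flavonoid biosynthesis (-0.12) and carbon fixation (-0.05) changed direction, and those of the other pathways and families named here kept theirs.

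More circRNAs were detected in leaf than in petiole. A lower total of back-spliced reads in petiole is argued against. The mean totals were 3727 in leaf and 3502 in petiole, and libraries thinned to equal totals still differed by -115.8. With totals this close, thinning could change little. It left the fewer reads of petiole inside the A06 block (mean 47 against 1844 in leaf) as they were. Outside the A06 block with plastid-type genes the difference was 21, and 9.6 at equal reads, so circles or junction-like reads from plastid sequences that align there may be the source of the excess. Relative to the linear counts of the block, leaf had 8.11 times the back-spliced reads of petiole, with no overlap between libraries. This cannot decide whether more linear reads from the block in leaf are the whole cause. The linear counts sum 77 assembled transcripts of the whole block, while the circRNAs lie in a part of it. The CP43-like gene, which holds 10 circRNAs, fell from 534 to 26.4 CPM, further than the block's share of linear counts (22.1% to 3.96%). A difference between the tissues in circle formation stays open and was not tested, and plastid genome sequence was not used here.

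There were 42 genes at 0 in every library of 1 tissue and at 500 or more counts in every library of the other, 22 at 0 in petiole and 20 at 0 in leaf, while 0 and 2 genes had totals of 1 to 3 counts. Reads assigned to other assembled transcripts at the same place are argued against for most of them, since 3 genes (7.14%) had overlapping transcripts with 10% or more of the level. A minimum below which the quantification lists 0 cannot be told apart from true absence: gene values of 1 to 3 counts were 0.981 times as frequent as values of 11 to 13 (2231 and 2275). By the rule set before this value was seen, a ratio under 1 went with such a minimum, and the question was left open only because the difference lies within counting error, an allowance added afterwards. A tissue difference stays open and was not tested further.

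Several circRNAs lay inside genes of repeat proteins: 17 in the extensin-2-like gene BraA04g030500.3C and 15 in a cell wall-plasma membrane linker gene (BraA05g025150.3C). In the extensin gene 14 of 17 circRNA lengths (82.4%, exact Clopper-Pearson interval 56.6 to 96.2) were multiples of 3 (exact binomial p = 4.66e-05), so in-frame repeats of the coding sequence, where reads could align across repeat units, are a candidate explanation. Of the other single-exon circRNAs inside genes 83 of 193 were (43.0%, exact p = 0.00582), fewer than in the extensin gene (Fisher's exact two-sided p = 0.00202) but not shown to differ from the linker gene (8 of 15, p = 0.59), and the repeats were not examined because no genome sequence was used here. Some of the 17 circRNAs of the extensin gene are typed as intron circRNAs. They also share ends (14 starts and 14 ends), so they are not independent, as the exact tests take them to be. Abundance of the host transcript is the other candidate, since across 273 host genes the number of circRNAs rose with the mean count of the gene (Spearman's rho 0.205, permutation p = 0.00037). Of these genes 259 had 1 circRNA, so the relation rests on the few with more, and genes without circRNAs were left out. No biological explanation was tested.

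The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. In 1 split, the real one, as many items were called for genes (17470, highest other split 1), for isoforms (15649, highest other 2) and for circRNAs (1, highest other 0). Every other split put libraries of both tissues on each side, so that the tissue difference widened the spread within its groups. Few calls could arise there, and no conclusion is drawn from the contrast.

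Of 21100 isoforms with at least 500 counts in 2 leaf libraries, 336 were at 0 in the other one, and of 23461 in petiole, 420 were. At the gene level these were 5 of 15906 and 4 of 17227. Of the 747 circRNAs found in 1 library, 114 had at least 10 reads there and the highest had 245. When circRNAs with ends within 10 bp of each other were merged, 705 of 849 were found in 1 library.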
